A study of Mus musculus with 6 samples.

How the data were processed

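Mature CD8 thymocytes were sorted by the authors from wild type mice, Tcf1-deficient mice and mice deficient for Tcf1 and Lef1, and total RNA was sequenced on an Illumina protocol, per the labels. The labels give 3 groups of 2 libraries. The design text says that the factors were deleted with CD4-Cre; whether libraries of a group came from separate mice is not stated there.

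The values used are the deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 column per library and 2 decimals. RSEM 1.2.21, FastQC and the mouse build mm9 are named in the submitters' processing notes. The aligner, the annotation and any filter are not given in the sources used here. RSEM divides reads that match several genes among them, so values of near-identical genes are uncertain. The table used here lists 16383 genes in alphabetical order, the last being Pcsk5. Genes later in the alphabet, including 78 of the 358 entries of the gene lists, are not analysed here. Sums over the listed genes (223930 to 230442 FPKM) are therefore not library totals, and all adjusted p-values and gene list tests are relative to the listed genes. 13 symbols that a spreadsheet had turned into dates were restored from the RefSeq accession in the same row. The reference annotation at hand is of a later mouse assembly than the files, so no coordinates are printed; it was used only for gene names, gene order and transcript lengths.

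The table holds no counts. Depth was read from low values of single-transcript genes of 400 to 1000 bases, with a fragment length of 200 bases assumed, as the number of fragments that best makes the values whole multiples of 1 fragment. Between 66.5% and 73.2% of the values lay within 0.25 of a whole number of fragments. The same search with transcript lengths shuffled among these genes gave 56.6% to 58.5% on average and at most 65.4% in 100 runs per library, and in each library its fit was below the observed one in all runs. That check was added after the depths were seen. The relative depth of the libraries ranged from 0.842 to 1. These depths are approximate, because RSEM's estimated counts need not be whole. No interval was computed from them, and no count test was run.

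Genes were kept with at least 1 FPKM in at least 2 of the 6 libraries, which left 6761 genes and set aside 9622. A pseudocount of 1 was added and the log2 values were fitted in limma 3.58.1 (R 4.3.3) with genotype as the only term, all 6 libraries in 1 fit, and moderated variances with a trend. This left 3 residual degrees of freedom per gene. The 3 comparisons were DKO against WT, Tcf1 KO against WT and DKO against Tcf1 KO, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Log2 changes on this scale understate the change of genes with low FPKM.

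The genes named in each comparison followed a rule: the targeted genes, the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap (provisional gene models left out), up to 4 changed members of each gene list, up to 2 of the most abundant members of a list with none, and a fixed set of lineage genes. A few further list members are named to complete a count, and 1 gene that the rule names is not reported here. The 23 gene lists were textbook lists: CD4 helper lineage, regulatory T cell, Th17, Th1 with Th2 and Tfh, CD8 lineage and cytotoxic, memory-like CD8, CD4 or CD8 fate regulators, mature thymocyte, immature double-positive thymocyte, Wnt targets, T cell receptor signalling, immediate early, inhibitory receptors, chemokine receptors and trafficking, interferon-stimulated, cell cycle, apoptosis and survival, heat shock, NK with NKT and γδ T cells, and B cell, myeloid, thymic stromal and erythroid markers. Lists with at least 3 tested members, 22 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01. Its p-values were adjusted over the lists of a comparison. Camera was run again with ranks and with an estimated correlation, which rests on the 3 residual degrees of freedom. No list passed with an estimated correlation in any comparison, so a call lost there does not tell a weak list from a strong one. Limma's fry, which does not compare a list with the other genes, was run beside camera. Samples, gene lists, the rule, the tests of these comparisons and the alternatives were fixed before the data were examined. Some tests of explanations and the gene families were chosen later, as stated with them.

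Overlap and correlation of the changes in the 2 comparisons with WT were set beside 100 simulations of unchanged groups against the same WT libraries. The count of Tcf1 KO changes that turned back in DKO was set beside 100 simulations in which the called Tcf1 KO changes were the same in DKO, the other genes had the WT mean in Tcf1 KO and their own mean in DKO. It was chosen after the count was seen, and so were 2 others with almost no genes turning back, DKO at the Tcf1 KO means (0.17 of 971 calls) and Tcf1 KO at the WT means (0.15 of 0.21 calls). The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 5 FPKM, median and quantile scaling, other variance models, only the groups compared, a change of at least 2-fold, the replicate number as a block, and each library left out in turn. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups.

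The model was tested on simulated data for DKO against WT on 6761 genes, with 200 changed genes in each of 5 runs. It recovered 58.4% of genes changed by 0.5 on the log2 scale, 92.4% at 1, 98.8% at 2 and 99.2% at 3. On average 5.93% of its calls were false. The changed genes were drawn from those better expressed in WT. Noise was normal, with variances drawn from the distribution that limma had fitted. These rates therefore check the model under its own assumptions, with far fewer changed genes than were called in the data. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.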

Results

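RNA was sequenced from mature CD8 thymocytes of mice, sorted as cells with a high level of TCRβ that carried CD8 and lacked CD69 and CD24. There were 3 genotypes with 2 libraries each: wild type (WT), Tcf1-deficient (Tcf1 KO) and deficient for both Tcf1 and Lef1 (DKO). Tcf1, encoded by Tcf7, and Lef1 are related HMG-box transcription factors that act in T cell development. The question set by the title is what the loss of these factors does to gene expression in mature CD8 thymocytes. Values are gene-level FPKM, and the table used here lists 16383 genes in alphabetical order ending at Pcsk5, so genes later in the alphabet, among them Tcf7, Runx3, Zbtb7b and Prdm1, are not analysed here. The table gives no read counts. The spacing of low FPKM values in short transcripts corresponded to about 50750000 to 60250000 fragments per library, so that 1 FPKM on a 2 kb transcript stood for about 91.4 to 108.5 fragments. Within a genotype the libraries correlated across genes at r = 0.9916 (WT), 0.9892 (Tcf1 KO) and 0.9856 (DKO) on the log2 scale. Errors of means are SD with n = 2, log2 changes are on the log2(FPKM + 1) scale with their standard error (SE), and p-values are from limma with Benjamini-Hochberg adjustment. The labels do not say that the libraries of a genotype came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

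Lef1 was checked first, since it is a targeted gene. Its level was 299 ± 24.2 FPKM in WT and 310.1 ± 1.97 FPKM in Tcf1 KO, a log2 difference of 0.05 ± 0.06 (adjusted p = 0.686). It was 130.6 ± 0.488 FPKM in DKO, and fell by 1.19 ± 0.06 on the log2 scale against WT (adjusted p = 0.000157). Gene-level FPKM includes exons outside any deleted part, so the remaining signal does not measure intact Lef1 transcript. Tcf7 is not analysed here, and the Tcf1 genotype therefore rests on the labels.

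The loss of both factors was compared with WT. DKO cells had 96.3 ± 46.1 FPKM of Cd4, the co-receptor of helper T cells, against 1.03 ± 0.537 FPKM in WT, a log2 rise of 5.52 ± 0.48 (adjusted p = 0.000516). Foxp3, the transcription factor of regulatory T cells, rose from 1.08 ± 0.163 to 21.7 ± 11.9 FPKM, by 3.34 ± 0.34 (adjusted p = 0.00088). The co-receptor genes of the sorted lineage stayed at high levels: Cd8a was at 580.7 ± 27.2 FPKM in WT and 525.7 ± 13.1 FPKM in DKO (adjusted p = 0.0686), and Cd8b1 at 754.6 ± 49.6 and 876.4 ± 68.0 FPKM (adjusted p = 0.0661). The Cd8b1 difference passed the test under median scaling (adjusted p = 0.0217) and without DKO replicate 1 (0.0356). The cytotoxic effector genes Gzma and Fasl rose as well, Gzma from 1.91 ± 0.707 to 82.0 ± 35 FPKM and Fasl, whose product is a ligand that triggers apoptosis, from 0.455 ± 0.0919 to 40.5 ± 1.31 FPKM. All 16 tested genes of the cell cycle list fell, among them Mki67, a marker of cycling cells, which went from 44.7 ± 3.1 to 0.805 ± 0.177 FPKM.

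**Figure D1:**
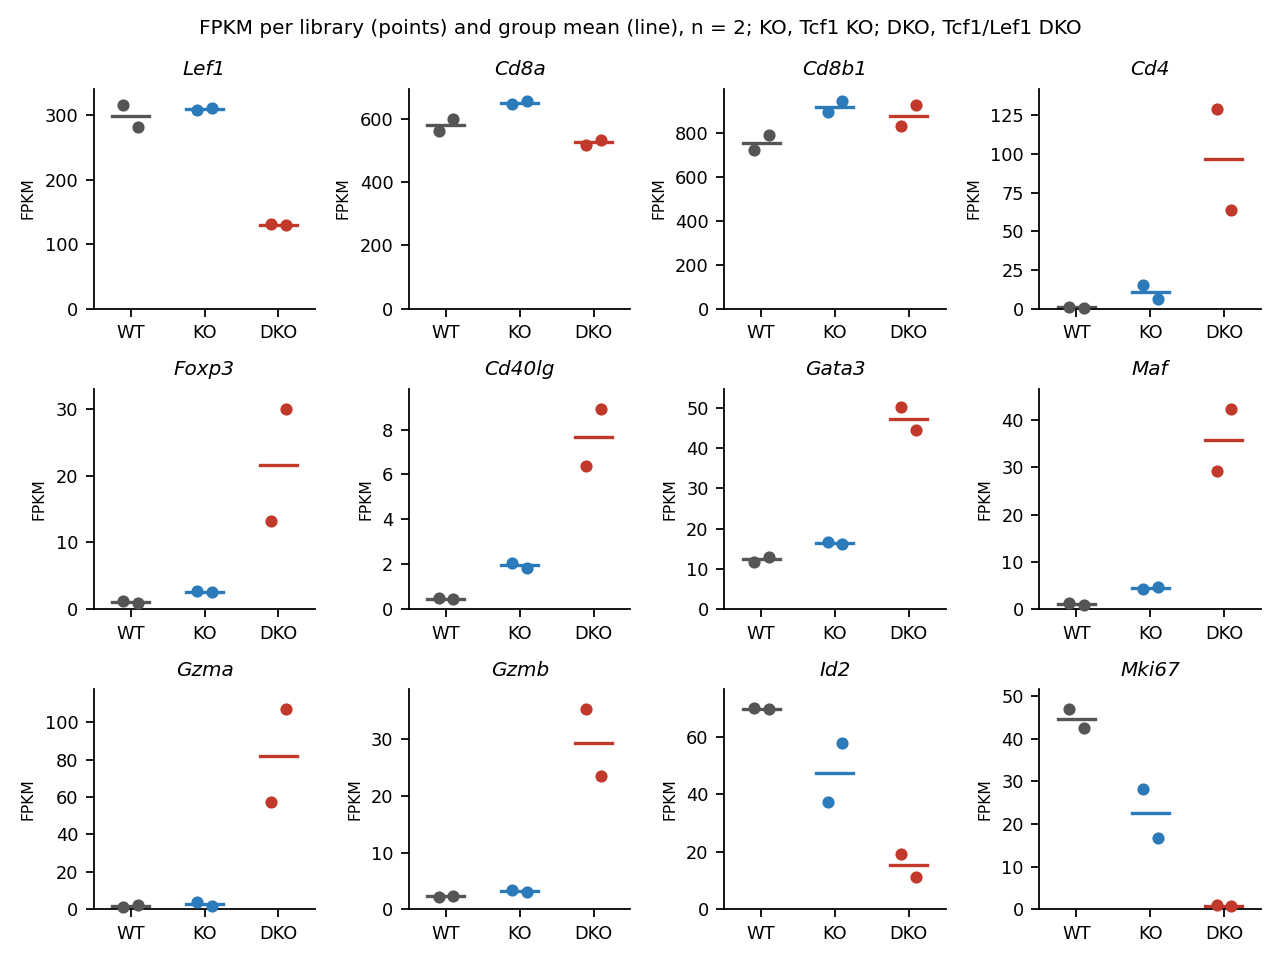
FPKM of 12 genes in each library (points) with the mean of each genotype (line), on linear axes that start at 0; KO is Tcf1 KO and DKO is the Tcf1 and Lef1 double deficiency, n = 2. Cd4 lies at 128.95 and 63.72 FPKM in the DKO libraries and below 16 FPKM in the other libraries.

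Of 6761 genes tested in DKO against WT, 1465 were higher and 1880 lower at adjusted p under 0.05, and 244 and 397 of these changed at least 2-fold on the log2(FPKM + 1) scale. The balance turned with scaling, to 1781 higher and 1617 lower under median scaling and 1817 and 1626 under quantile scaling. The largest rises after Cd4, Fasl and Gzma were in Il18r1, a subunit of the interleukin-18 receptor (4.17 ± 0.12), the transcription factor Maf (4.16 ± 0.21), Nrp1, the co-receptor neuropilin (3.82 ± 0.09), the growth factor receptor Igf1r (3.72 ± 0.08) and the inhibitory receptor Lag3 (3.66 ± 0.16). Further large rises were in P2ry1, which is close to 0 in WT (0.02 ± 0.0141 FPKM) and 10.6 ± 5.9 FPKM in DKO, in the chemokine receptor Ccr2 (3.29 ± 0.20) and in the granzyme Gzmb (3.19 ± 0.19). The 12 largest falls included Igfbp4, a binding protein of insulin-like growth factors (-5.37 ± 0.18), Gramd3 (-5.10 ± 0.18), Mki67 (-4.66 ± 0.23), Folr4 (-4.42 ± 0.11) and Mxd3, of the MYC network (-4.27 ± 0.20). The cyclins Ccna2 (-4.20 ± 0.21) and Ccnb2 (-4.19 ± 0.20), Birc5 (-4.14 ± 0.25), the activating receptor Cd226 (-3.93 ± 0.16), Gpr97 (-3.87 ± 0.10) and Gpr55 (-3.84 ± 0.13) were also among them. Every gene of this paragraph passed adjusted p = 0.00088 or lower, and its DKO libraries lay on 1 side of both WT libraries.

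Helper lineage genes moved in both directions. Of 8 tested members of the CD4 helper list, 5 rose and 3 fell, the same counts when adjusted over the list alone. Beside Cd4, the risers included Cd40lg, a helper ligand for B cells (2.56 ± 0.16, from 0.455 ± 0.0354 to 7.66 ± 1.8 FPKM), Gata3 (1.86 ± 0.08) and the chemokine receptor Ccr4 (1.75 ± 0.20). Il6ra (-1.55), Cd5 (-0.50) and Icos (-0.21) fell. Of 10 tested regulatory T cell genes, 4 rose and 5 fell, again also when adjusted over the list alone. Nrp1, Foxp3, Itgae (1.07) and Il2ra (0.93) rose, whereas Folr4, Gpr83 (-2.86 ± 0.17), Ikzf2 (-1.93), Ikzf4 (-1.10) and Capg (-0.79) fell. Ctla4, the remaining member, was at 2.35 ± 0.262 FPKM in WT and 2.16 ± 0.474 FPKM in DKO (-0.09 ± 0.14, adjusted p = 0.629). In the list of Th17 genes, 2 of 4 tested members rose (Maf and Il17re, 2.86 ± 0.19) and Ahr fell (-0.95 ± 0.13). The known study drew attention to Cd4, Foxp3 and Ctla4 in these cells, so the helper, regulatory and Th17 lists were not chosen blind to it.

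Among 14 tested genes of the CD8 and cytotoxic list, 5 rose (Fasl, Gzma, Gzmb, Itgae and Cd7) and 3 fell, namely Crtam (-2.79 ± 0.21), the killer lectin receptor Klrd1 (-1.41) and the transcription factor Eomes (-1.73 ± 0.17), with the same counts when adjusted over the list alone. Of 7 tested genes of memory-like or innate-like CD8 cells, 2 rose and 4 fell, the falls being in Ly6c2 (-2.94 ± 0.16), Id2 (-2.17 ± 0.29), Eomes and Il2rb (-0.67). Reads of Ly6c2 can be shared with its close copy Ly6c1, and those of Gzmb with related granzymes, so these values are uncertain. The mature thymocyte list had 5 members higher and 2 lower of 9. Klf2, a factor of thymic exit, rose from 247.4 ± 7.65 to 549.8 ± 31.6 FPKM and Cd55 by 2.41 ± 0.18, whereas Ccr7 fell from 211.5 ± 4.5 to 65.4 ± 14.1 FPKM. H2-Q7 was lower in DKO (-1.99 ± 0.65, adjusted p = 0.0485), a call that ended without WT replicate 1 (adjusted p = 0.134), without WT replicate 2 (0.176), without Tcf1 KO replicate 1 (0.0793) or without Tcf1 KO replicate 2 (0.0794). Of 10 tested double-positive thymocyte genes 4 rose, with Aqp11 (1.77 ± 0.09), Arpp21 (1.77 ± 0.18) and Ccr9 (1.11 ± 0.06) leading, and 2 fell. Myb (-3.15 ± 0.23) led the 5 falls among 11 fate regulators, of which Gata3 and Ikzf1 (0.62 ± 0.10) rose.

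The cell cycle list had a median log2 change of -3.00 and a camera adjusted p of 6.18e-09 in DKO against WT. With an estimated correlation its adjusted p was 0.696, which was also the lowest of any list in that version. Of 17 tested interferon-stimulated genes 12 fell, also when adjusted over the list alone, with a median of -0.94 (camera adjusted p = 0.0147, and adjusted p = 0.738 with an estimated correlation). Ifi27l2a went from 459.0 ± 19.7 to 158.3 ± 42.3 FPKM, and Isg20 fell by 1.14. The falls in Oas1a (-2.08), Mx1 (-1.48) and Oas2 (-1.40) rested on DKO libraries that lay apart, with Oas1a at 3.16 ± 3.54 and Mx1 at 5.55 ± 3.79 FPKM. Their calls ended without WT replicate 1 (adjusted p = 0.112, 0.0856 and 0.082) or WT replicate 2 (0.142, 0.13 and 0.109), that of Oas1a also without either Tcf1 KO library (0.0584), and that of Oas2 without DKO replicate 2 (0.0571). Among Wnt targets, Axin2 rose (1.30 ± 0.08), whereas Ccnd2 (-1.62 ± 0.13), Myc (-1.30 ± 0.12) and Lef1 itself fell, making 3 falls of 5 tested. In the list of immediate early genes, Ier3 rose (2.96 ± 0.12) and 7 of 17 fell, led by Nr4a3 (-1.37 ± 0.14), Myc and Nr4a1 (-1.24 ± 0.17). Of 6 inhibitory receptor genes 3 rose and 2 fell, with Lag3 and Cd160 (-2.75 ± 0.09) at the ends. Of 14 chemokine receptor and trafficking genes 7 rose, Ccr2 and Ccr4 first, and 3 fell, led by Ccr8 (-2.73 ± 0.14). Of T cell receptor signalling genes 5 rose and 4 fell of 13, and of apoptosis and survival genes 5 and 4 of 16. In the heat shock and dissociation stress list 1 rose and 2 fell of 12, and 1 rose and 1 fell over the list alone. Hspa1b (1.65 ± 0.30), which can share reads with Hspa1a, and the stress-induced Ddit4 (-1.79 ± 0.26) were at the ends. The other fall, of Hspe1 (-0.67), did not pass under median scaling (limma adjusted p = 0.0576) and was -0.36 without DKO replicate 2. Of 4 Th1, Th2 and Tfh regulators 1 rose (Gata3) and 2 fell. In that list the median was negative (-0.12) while the mean (0.13) and the camera direction were positive.

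Markers of other cells were also tested. Of the tested members, 1 of 3 B cell markers (Cd79b, 0.29 ± 0.09, from 18 ± 0.969 to 22.2 ± 1.77 FPKM) and 2 of 3 thymic stromal markers (Cdh5, 0.74 ± 0.13, and Epcam, 0.54 ± 0.14) rose, and 2 of 4 myeloid markers fell (Cd74, -0.79 ± 0.16, and Bst2, -0.94 ± 0.20, which is also interferon-stimulated). The calls of Cd79b and Epcam ended without WT replicate 1 (adjusted p = 0.184 and 0.12), without WT replicate 2 (0.0917 and 0.0523) or without DKO replicate 2 (0.138 and 0.0775). The call of Cd74 ended without WT replicate 1 (0.0632) and that of Bst2 without WT replicate 2 (0.0717). Of the lists of B cell, myeloid, stromal and erythroid markers, 10, 12, 8 and 12 members did not pass the expression filter, and none of these exceeded 1.04 FPKM in any library. Car2, the 1 erythroid marker tested, rose from 10.1 ± 0.0354 to 16.3 ± 0.0778 FPKM. In the list of NK, NKT and γδ T cell markers, Il18r1 and 5830411N06Rik (3.26 ± 0.24) rose and Cd160 fell, of 4 tested.

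The other 20 of 22 lists tested in DKO against WT had camera adjusted p from 0.379 to 0.905. By fry the cell cycle list passed (adjusted p = 0.00427), and so did many of these 20. Among them were the CD4 helper list, upward, and the Wnt target list, downward (0.00413 each). The targeted gene Lef1 is 1 of the 5 tested members of the Wnt target list, which was not tested without it. The Th17 list, upward (0.00684), and the memory-like CD8 list, downward (0.0136), passed too. So did the apoptosis and survival list (fry adjusted p = 0.0401) and the thymic stromal list (0.0413), both upward. Fry does not compare a list with the other genes, and 49.5% of all tested genes were called in DKO against WT. The interferon-stimulated (0.0792) and regulatory T cell (0.0931) lists were among those that did not pass by fry. Without WT replicate 1 the number of changed genes was 2219, and without WT replicate 2 it was 2066, against 3345 with all libraries. Of 81 named calls, 69 passed the test whichever library was left out.

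**Figure D2:**
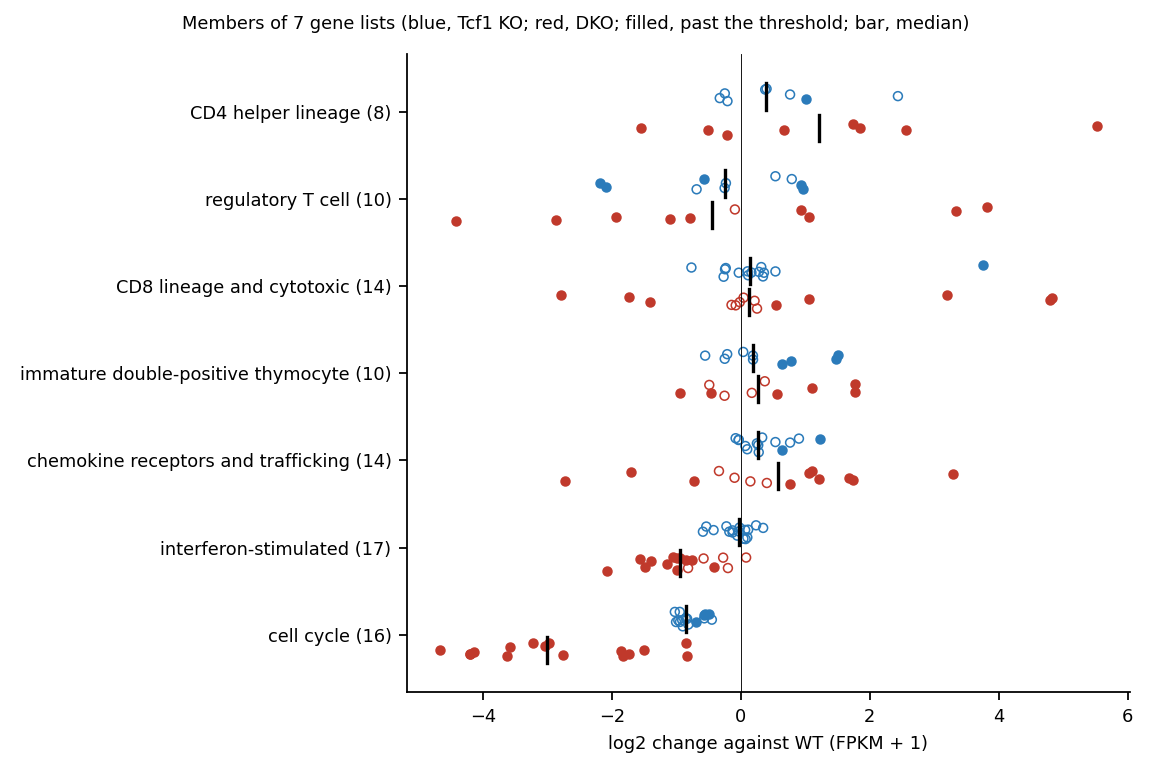
Log2 change against WT, on the log2(FPKM + 1) scale, of the tested members of 7 gene lists, with the number of members in brackets; blue points are Tcf1 KO and red points DKO, filled points passed adjusted p under 0.05, and bars are medians. The cell cycle medians are -0.84 in Tcf1 KO and -3.00 in DKO, and the interferon-stimulated medians -0.03 and -0.94.

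The loss of Tcf1 alone was compared with WT. Fasl rose from 0.455 ± 0.0919 to 18.7 ± 0.12 FPKM (3.76 ± 0.07, adjusted p = 5.58e-05) and Il18r1 from 9.93 ± 1.15 to 50.6 ± 7.34 FPKM (2.24 ± 0.12, adjusted p = 0.00279). Dntt, the terminal transferase of immature thymocytes, rose from 8.56 ± 0.757 to 26.4 ± 2.74 FPKM and Nt5e, the ectoenzyme CD73, from 13.8 ± 1.98 to 47.6 ± 2.23 FPKM. The phosphodiesterase family gene Gdpd3 fell from 34.3 ± 2.62 to 1.74 ± 0.0354 FPKM (-3.69 ± 0.14, adjusted p = 0.00066), and Folr4 from 40.4 ± 4.61 to 8.06 ± 0.587 FPKM (-2.19 ± 0.11). The call of Dntt ended without WT replicate 2 (adjusted p = 0.0543) and that of Nt5e without Tcf1 KO replicate 2 (0.0503). Cd4 was at 10.7 ± 6.22 FPKM against 1.03 ± 0.537 FPKM in WT, which did not pass the test (2.44 ± 0.48, adjusted p = 0.0689). With the replicate number as a block this difference passed (limma adjusted p = 0.00972).

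In Tcf1 KO against WT 90 genes were higher and 51 lower, and 34 and 13 of these changed at least 2-fold. The other large rises were in Pcsk1, a proprotein convertase (2.46 ± 0.16), the laminin subunit Lamc1 (2.11 ± 0.08), Eno1b (2.08 ± 0.32), Dennd5a (1.74 ± 0.10), Coro2a (1.58 ± 0.22), Papss2 (1.49 ± 0.13), Arpp21 (1.47 ± 0.18) and Maf (1.44 ± 0.21). The other large falls were in Eif3j2 (-3.58 ± 0.24), Gpr83 (-2.09 ± 0.17), Dapl1 (-1.92 ± 0.12), Gabrr2 (-1.53 ± 0.20), Igfbp4 (-1.42 ± 0.18), Hopx (-1.40 ± 0.12), the lamin gene Lmna (-1.23 ± 0.16), Cdkn3 (-1.03 ± 0.14), Lcn4 (-1.02 ± 0.13) and Cpm (-0.89 ± 0.11). Eno1b and Eif3j2 can share reads with Eno1 and Eif3j1, so their values are uncertain. Of the 24 largest changes, 15 calls ended without WT replicate 1 (adjusted p from 0.0541 to 0.207), 15 without WT replicate 2 (0.0536 to 0.238), 8 without Tcf1 KO replicate 1 (0.0628 to 0.129) and 16 without Tcf1 KO replicate 2 (0.0503 to 0.165). That of Eno1b also ended without either DKO library (0.056 and 0.0562).

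Of the 16 cell cycle genes, 4 fell in Tcf1 KO (Mcm5, -0.69 ± 0.08, Mcm2, -0.57 ± 0.09, Ccne1, -0.56 ± 0.06, and Mcm6, -0.49 ± 0.08) and 16 fell when adjusted over the list alone, with a median of -0.84 (camera adjusted p = 2.44e-11, and adjusted p = 0.743 with an estimated correlation). These 4 calls ended without WT replicate 1 (adjusted p from 0.171 to 0.231), without WT replicate 2 (0.194 to 0.286) or without Tcf1 KO replicate 2 (0.0697 to 0.149), and that of Mcm6 also without either DKO library (0.056 and 0.0554). Median and quantile scaling ended the calls of Mcm2 (0.0544 and 0.0505) and Mcm6 (0.0597 and 0.0523). Mki67 was at 22.5 ± 8.17 FPKM in Tcf1 KO, which did not pass the test against WT (adjusted p = 0.0884). Of 4 tested NK, NKT and γδ T cell markers, 3 rose (Il18r1, 5830411N06Rik, 2.10 ± 0.24, and Cd160, 0.79 ± 0.09), the same count over the list alone (camera adjusted p = 2.43e-05, and adjusted p = 0.377 with an estimated correlation). Among 14 chemokine receptor and trafficking genes, P2rx7 (1.23 ± 0.18) and Ccr9 (0.64 ± 0.06) rose, and 5 did when adjusted over the list alone (camera adjusted p = 0.00299, and adjusted p = 0.743 with an estimated correlation). The camera calls of both of these lists also ended without the filter on low values (adjusted p = 0.177), where the median of the NK, NKT and γδ T cell list was -0.0038. Of 10 double-positive thymocyte genes 4 rose, namely Dntt, Arpp21, Ccr9 and Aqp11 (0.78 ± 0.09), with a camera adjusted p of 0.0488, and an adjusted p = 0.743 with an estimated correlation. That call also ended without WT replicate 2 (adjusted p = 0.188), without Tcf1 KO replicate 1 (0.245) or without either DKO library (0.0683 and 0.0678). Without WT replicate 1, WT replicate 2 or Tcf1 KO replicate 2, the adjusted p was 0.153, 0.0889 and 0.0561 for 5830411N06Rik, 0.135, 0.165 and 0.114 for Cd160, 0.14, 0.146 and 0.0503 for Ccr9, and 0.258, 0.231 and 0.0503 for P2rx7. It was 0.153, 0.198 and 0.12 for Aqp11 and 0.138, 0.177 and 0.0865 for Arpp21. Dntt ended without WT replicate 2 (0.0543). Without Tcf1 KO replicate 1 the calls of P2rx7 (0.0503), Aqp11 (0.0549) and Arpp21 (0.0628) ended, as did P2rx7 without either DKO library (0.0552) and under quantile scaling (0.0505).

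Lineage genes were also read in Tcf1 KO. Cd40lg rose from 0.455 ± 0.0354 to 1.94 ± 0.177 FPKM (adjusted p = 0.0461), the 1 gene past the test among 8 of the CD4 helper list, where 5 rose and 2 fell over the list alone. That call ended without either WT library (adjusted p = 0.251 and 0.279) or either Tcf1 KO library (0.134 and 0.147). Foxp3 was at 2.60 ± 0.106 FPKM (0.79 ± 0.34, adjusted p = 0.267, which passed at 0.0352 and 0.0358 without DKO replicate 1 or 2), Ctla4 at 1.08 ± 0.113 FPKM (adjusted p = 0.0734), Cd8a at 651.2 ± 6.9 FPKM (adjusted p = 0.153) and Cd8b1 at 916.7 ± 34.3 FPKM (adjusted p = 0.118). Il2ra (0.96 ± 0.10) and Nrp1 (0.94 ± 0.09) rose while Folr4 and Gpr83 fell among 5 changed regulatory T cell genes. Without WT replicate 1, WT replicate 2 or Tcf1 KO replicate 2, the adjusted p was 0.143, 0.167 and 0.114 for Il2ra and 0.109, 0.073 and 0.0706 for Nrp1. The call of Gpr83 ended without WT replicate 1 (0.0541) or Tcf1 KO replicate 2 (0.0648). Car2 fell from 10.1 ± 0.0354 to 5.4 ± 0.0495 FPKM, a call that ended without WT replicate 1 (0.103), WT replicate 2 (0.0889) or Tcf1 KO replicate 2 (0.0561). The interferon-stimulated genes, with Ifi27l2a at 342.6 ± 16.9 FPKM and Bst2 at 162.2 ± 22.3 FPKM, had no member past the test by limma, a count that was also 0 over the list alone and 0 at unadjusted p under 0.05. Ifi27l2a was lower at an adjusted p = 0.041 and 0.0411 without DKO replicate 1 or 2. By fry the NK, NKT and γδ T cell list alone passed in Tcf1 KO against WT (adjusted p = 0.0103), with the cell cycle list at 0.0799. In all, 13 of the 22 lists tested had no member past the test. The 18 lists without a camera call had camera adjusted p from 0.0617 to 0.974. The lowest of these, of the CD8 and cytotoxic list, passed without WT replicate 2 (0.00307) or without DKO replicate 1 or 2 (0.0273 and 0.0268).

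At unadjusted p under 0.05 the Tcf1 KO comparison had 1429 genes, and the count of 141 at adjusted p under 0.05 was 12 without WT replicate 1, 13 without WT replicate 2 and 12 without Tcf1 KO replicate 2. Without Tcf1 KO replicate 1 it was 134, of which 43 were higher and 91 lower. Fasl, Il18r1, Lamc1, Gdpd3 and Folr4 were the 5 of 37 named calls that passed whichever library was left out.

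The loss of Lef1 on top of Tcf1 was read from DKO against Tcf1 KO, which also tests whether the changes from WT differ between the genotypes. Gzma rose from 2.75 ± 1.6 to 82.0 ± 35 FPKM (4.47 ± 0.41, adjusted p = 0.0011), Lag3 from 1.53 ± 0.0919 to 23.2 ± 4.86 FPKM (3.24 ± 0.16, adjusted p = 0.000273) and Cd4 from 10.7 ± 6.22 to 96.3 ± 46.1 FPKM (3.09 ± 0.48, adjusted p = 0.00576). Foxp3 rose by 2.55 ± 0.34 (adjusted p = 0.00351) and Maf by 2.72 ± 0.21 (adjusted p = 0.00077). Cd160, an immunoglobulin-family receptor that had risen in Tcf1 KO, fell from 28.6 ± 1.38 to 1.53 ± 0.163 FPKM. Cd8a fell by 0.31 ± 0.05 (adjusted p = 0.00765), while Cd8b1 differed by -0.07 ± 0.08 (adjusted p = 0.544).

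In DKO against Tcf1 KO 1072 genes were higher and 1527 lower, and 157 and 293 of these changed at least 2-fold. Here too the balance turned, to 1312 higher and 1271 lower under median scaling and 1331 and 1302 under quantile scaling. Other large rises were in Ccr2 (3.19 ± 0.20), Ier3 (2.89 ± 0.12), Nrp1 (2.88 ± 0.09), Eif3j2 (2.87 ± 0.24), Gzmb (2.83 ± 0.19), P2ry1 (from 0.6 ± 0.212 to 10.6 ± 5.9 FPKM) and Igf1r (2.62 ± 0.08). Other large falls were in Gramd3 (-5.14 ± 0.18), Gpr97 (-4.00 ± 0.10), Igfbp4 (-3.94 ± 0.18), Cd226 (-3.76 ± 0.16), Gpr55 (-3.70 ± 0.13), Mki67 (-3.66 ± 0.23), Amica1 (-3.34 ± 0.07), Acvrl1, a receptor of the TGF-β family (-3.32 ± 0.13), Ccnb2 (-3.29 ± 0.20) and Mxd3 (-3.24 ± 0.20).

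Of the 16 cell cycle genes, 16 fell in DKO against Tcf1 KO, with a median of -2.11 (camera adjusted p = 9.25e-09, and adjusted p = 0.887 with an estimated correlation). By fry the cell cycle list, downward, and the CD4 helper list, upward, were among those that passed (adjusted p = 0.00933 each). The interferon-stimulated list did not pass by fry (0.112). Of 17 interferon-stimulated genes 9 fell, and 13 over the list alone, with a median of -0.83 (camera adjusted p = 0.00327, and adjusted p = 0.887 with an estimated correlation). Oasl2 (-1.34 ± 0.28), Ifi27l2a (-1.13 ± 0.17) and Isg20 (-1.02 ± 0.12) were among those that fell, and the camera call ended without Tcf1 KO replicate 1 (adjusted p = 0.0563), as did the call of Oasl2 (0.0796). In the CD4 helper list 5 of 8 rose, led by Cd4, Cd40lg (1.54 ± 0.16) and Gata3 (1.48 ± 0.08), and Il6ra fell (-1.95 ± 0.13). Of 10 regulatory T cell genes 4 rose and 5 fell. Ctla4 rose from 1.08 ± 0.113 to 2.16 ± 0.474 FPKM (adjusted p = 0.0227), a call that ended without Tcf1 KO replicate 1 (adjusted p = 0.0965), without Tcf1 KO replicate 2 (0.0633) or without DKO replicate 2 (0.0689). Among 14 CD8 and cytotoxic genes 4 rose and 4 fell, with Crtam (-2.56 ± 0.21) and Eomes (-1.49 ± 0.17) leading the falls. Dntt fell from 26.4 ± 2.74 to 9.76 ± 0.573 FPKM and Mns1 by 0.98 ± 0.11, whereas Aqp11 (0.99 ± 0.09) and Ccr9 (0.47 ± 0.06) rose, among 10 double-positive thymocyte genes. Klf2 (1.25 ± 0.07) and Cd55 (1.91 ± 0.18) rose and Ccr7 fell (-1.66 ± 0.14).

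The other 20 lists tested in DKO against Tcf1 KO had camera adjusted p from 0.261 to 0.908, and of these the heat shock list (0.838) passed without DKO replicate 1 (0.0372). The number of changed genes was 2599 with all libraries, 1583 without Tcf1 KO replicate 1 and 1602 without Tcf1 KO replicate 2.

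**Figure D3:**
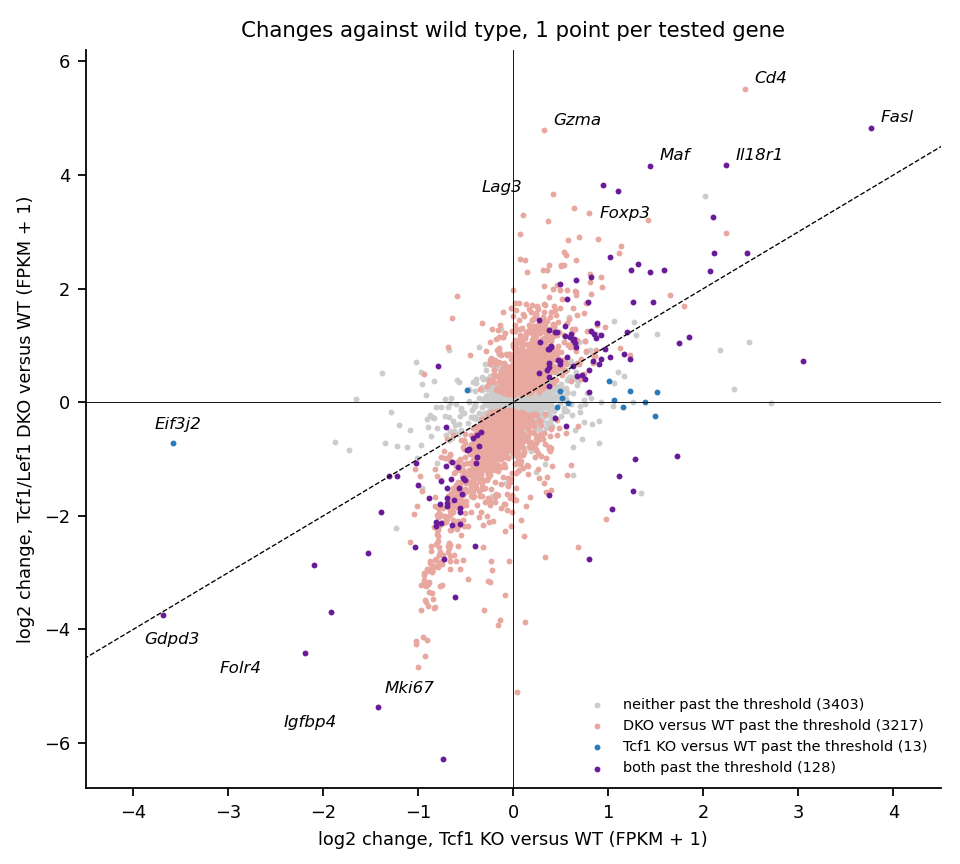
Log2 change against WT of each of 6761 tested genes, on the log2(FPKM + 1) scale, with Tcf1 KO on the x axis and DKO on the y axis; colours give the comparisons in which a gene passed adjusted p under 0.05, and the dashed line marks equal changes. Cd4 lies at 2.44 and 5.52, Fasl at 3.76 and 4.83, and Eif3j2 at -3.58 and -0.72.

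Genes that changed with the loss of Tcf1 were compared with those that changed with the loss of both factors. Of 141 genes changed in Tcf1 KO, 118 changed in the same direction in DKO against WT, 70 of them higher and 48 lower, 10 changed in the opposite direction and 13 did not pass the test. Of the 118, 88 also changed further in DKO against Tcf1 KO, among them Il18r1, Maf, Igfbp4 and Folr4. Another 30 of the 141 changed back toward or past WT in DKO against Tcf1 KO. Both comparisons use the same Tcf1 KO libraries, so chance alone can add to that count. A set of 100 simulations kept the 141 Tcf1 KO changes in DKO and gave the other genes no Tcf1 KO change. There 5.65 of 135 calls per run turned back on average, and at most 11. The called changes entered at their observed size, which selection can inflate, so the simulated count may be too low. The 30 observed genes included Dntt, Nt5e (-2.66) and Cd160, which fell, and Car2 (1.43), which rose. The 141 calls behind these counts were 12 without WT replicate 1, 13 without WT replicate 2 and 12 without Tcf1 KO replicate 2. Independent lists of these sizes would share 19.5 higher and 14.2 lower genes, and unchanged groups simulated against the same WT libraries shared 0.01 and 0. Unchanged groups give almost no calls, so the simulated counts do not measure overlap that the shared WT libraries add. Across genes, which are not independent replicates, the log2 changes of the Tcf1 KO and DKO comparisons correlated at r = 0.638 (rho = 0.638), against 0.498 in simulated unchanged groups (range 0.361 to 0.59 in 100 runs). Their covariance was 0.136 against 0.0118 in the simulation, a difference of 0.124. The simulated groups shared their WT libraries as well, and their covariance was at most 0.0166. These values argue against the spread between the shared WT libraries as the source of the covariance difference. An offset common to both WT libraries was not simulated and stays open. The 2 WT libraries were not split, since each part would hold 1 library. Part of the overlap in calls and of the correlation may come from the shared WT libraries. Without Tcf1 KO replicate 2 the correlation was 0.554.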

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

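The alternatives were planned before the data were examined. At least 2-fold changes cut the counts to 641 genes (DKO against WT), 47 (Tcf1 KO against WT) and 450 (DKO against Tcf1 KO), and without the filter the Tcf1 KO count was 39 while more genes were tested; the cause of that lower count was not tested. Leaving out 1 library gave 2066 to 3115, 12 to 177 and 1583 to 2275 genes, where fewer samples leave fewer degrees of freedom. Without Tcf1 KO replicate 1 the Tcf1 KO count was 134, of which 64 were among the 141. The correlation of the changes was 0.591 with a pseudocount of 0.1 and 0.554 to 0.648 with 1 library left out; the cause was not tested. Median and quantile scaling moved the median of all genes by less than 0.1 and the higher share of DKO calls against WT from 43.8% to 52.4% and 52.8%. No named or list call reversed. Of the named calls 69 of 81, 5 of 37 and 70 of 83 held in every setting that tested the gene, in the same order. The 2-fold bound was applied only to the gene counts, and genes that a filter removed were not tested under it. All 8 camera calls ended with an estimated correlation, where the lowest adjusted p of any list was 0.696, 0.377 and 0.887, in the same order. That version passed no list, so these losses do not rank the lists. With the replicate number as a block the counts were 3571, 151 and 2812, against 3345, 141 and 2599 without it. Deviations of same-numbered libraries correlated at 0.0454 (WT with Tcf1 KO), 0.154 (WT with DKO) and 0.147 (Tcf1 KO with DKO). The labels give these libraries only a shared number, and these values do not settle whether they also shared a batch. Under the block Cd4 passed in Tcf1 KO against WT (adjusted p = 0.00972), and Cd8a (0.0481) and Cd8b1 (0.0164) in DKO against WT, by limma. In Tcf1 KO against WT the block ended the calls of Maf (0.0535), Cd40lg (0.0549), P2rx7 (0.0521), Mcm2 (0.0563) and Mcm6 (0.0521). Foxp3 passed in Tcf1 KO against WT with only the groups compared (adjusted p = 0.0424). The steps in FPKM put 1 fragment on a 2 kb transcript at about 0.01 FPKM, so depth limits genes below the filter most.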

Other observations

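The gene families below were chosen after the data were seen, as were the tests of regulatory, double-positive and CD4 single-positive cells and of double-positive markers against cell cycle genes. Among 92 families grouped by symbol stem, the 8 tested Gimap genes, GTPases of lymphocytes, all rose in DKO against WT, with a median log2 change of 0.56 (camera adjusted p = 0.00128, and adjusted p = 0.683 with an estimated correlation). All 8 also rose under median and quantile scaling. Of the Mrpl genes, of mitochondrial ribosomes, 34 of 48 fell (median -0.37, camera adjusted p = 4.19e-05), as did 12 of 13 Ndufa and 10 of 10 Ndufb genes, of respiratory complex I (adjusted p = 0.00128 each). With an estimated correlation the adjusted p was 0.683 for each of these families, in a version that passed no gene list in any comparison. The Cox family had 17 lower and 1 higher of 21 (camera adjusted p = 0.00507, and adjusted p = 0.683 with an estimated correlation), with 16 and 15 lower under the scalings. The Ndufs, Atp and Coq families did not pass: Ndufs had 5 lower and 1 higher of 8 and Atp 22 lower and 9 higher of 55 (camera adjusted p = 0.212 each), and Coq 2 lower of 9 (0.224). Under median scaling 30 Mrpl, 12 Ndufa and 9 Ndufb genes were lower, and under quantile scaling 30, 12 and 10. Of the 8 tested Klf genes 6 rose and 1 fell, also under both scalings (median 0.72, camera adjusted p = 0.0187, and adjusted p = 0.683 with an estimated correlation).

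Cd4 and Foxp3 were higher in DKO than in WT in a sort for CD8 cells without CD69 or CD24. The 9 other tested regulatory T cell list members had a median change of -0.79, with 3 higher and 5 lower. This median cannot exclude an added minority of regulatory T cells, since members such as Folr4 (40.4 FPKM) and Gpr83 (6.49 FPKM) were expressed in WT. Of members low in WT, Nrp1 rose from 1.3 to 31.5 FPKM and Ctla4 did not rise. In DKO, Folr4 and Ctla4 stood at 0.94 and 2.16 FPKM beside 21.7 FPKM of Foxp3. These levels argue only against regulatory T cells with usual levels of Folr4 and Ctla4. Regulatory cells whose markers were themselves altered by the genotype stay open. List members such as Tnfrsf18, Tnfrsf4 and Tigit were not analysed. Double-positive thymocytes, which the CD24 and CD69 gate would remove, are argued against as the source of Cd4, because their 8 markers under 30 FPKM in Tcf1 KO moved by a median of 0.123 (95% bootstrap interval -0.983 to 0.371) in DKO against Tcf1 KO while Cd4 rose by 3.09; this subset was taken after the test on all 10 markers had been seen, which gave 0.123 (-0.46 to 0.381). CD4 single-positive cells, which the gate on CD8 would remove, cannot be told apart from expression within CD8 cells by these values. In DKO against WT Cd8b1 differed by 0.215 and Cd8a by -0.143, neither past the test in the main model. With the replicate number as a block both passed, Cd8a lower and Cd8b1 higher. Against Tcf1 KO, Cd8a was lower in DKO past the test, while Cd8b1 did not pass. A small share of CD4 single-positive cells would barely lower either gene. Expression of Cd4 and Foxp3 in CD8 cells that lack both factors remains a hypothesis that these data leave untested.

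Cell cycle genes were lower in DKO than in WT, with Tcf1 KO between. A lower share of immature double-positive cells in DKO is argued against, because the 10 tested double-positive markers had a median change of 0.273 (95% bootstrap interval -0.456 to 1.16) against -3.00 for the cell cycle genes. A scaling artefact is argued against by a test set before the result: all 16 members stayed lower under both median and quantile scaling, with medians of -2.95 and -2.78. Other explanations stay open and were not tested, a lower share of cycling cells and lower expression within each cell among them.

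DNA of the targeted strain that flanks a deleted gene could place changed genes near it. Of 100 tested neighbours of Tcf7, 1% changed in Tcf1 KO against WT and 2.12% of the other genes (Fisher's exact test, two-sided, p = 0.725), and of 93 neighbours of Lef1, 38.7% and 38.5% in DKO against Tcf1 KO (p = 1). The bound set beforehand, an odds ratio of at most 1, was met for Tcf7 (0.467), but its 95% interval, added after that value was seen, ran from 0.0116 to 2.71; for Lef1 it was 1.01 (0.644 to 1.56). Flanking DNA therefore cannot be told apart from chance at either locus, and genes after Pcsk5 in the alphabet were not among the neighbours.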
